A study of Penicillium oxalicum with 10 samples.

How the data were processed

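Mycelia of Penicillium oxalicum were profiled by digital gene expression sequencing in 10 libraries, 1 from the wild type and 1 from each of 9 strains labelled as deletions of flbA, flbB, flbC, flbD, flbE, wetA, abaA, stuA and swi6. Per the labels, conidia were grown in modified Czapek medium with 2% glucose for 20 h at 30 °C, and the mycelia were then moved to new medium for 48 h, filtered, and RNA was extracted with the RNAiso reagent. Per the submitters' processing notes, CASAVA 1.8 was used on the sequencer output. The aligner, the genome build and the gene annotation version are not given in the sources used here. No strain has a replicate.

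The deposited table lists 9859 genes by locus number with a coding length and annotation text. For each library the authors deposited the count of uniquely placed reads per gene, the RPKM (reads per kilobase of coding length, scaled by the read total) and, in percent, the part of each gene covered by reads. In all 10 libraries the counts summed to the total in the file headers, and RPKM recomputed from count, length and total differed from the deposited value by a relative gap of at most 2.57e-08. The deposited lengths are whole multiples of 3 for 9856 genes. A dash was read as 0. Annotation text gave an informative product or KEGG name for 3524 genes, of which 3443 passed the filter below, and the product column reads hypothetical protein for 9469 genes.

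Read totals were 5151034 in wild type, 3103231 in the flbA, 6891532 in the flbB, 4444141 in the flbC, 7597848 in the flbD, 7264479 in the flbE, 6612428 in the wetA, 7037725 in the abaA, 7108299 in the stuA and 5609486 in the swi6 deletion library. A floor of 3 reads on a gene of 1 kilobase is worth between 0.395 RPKM in the library labelled flbD deletion and 0.967 RPKM in the flbA deletion library. Reads carry no molecular identifiers.

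The comparisons, filters, gene lists and the rule for named genes were chosen before the data were examined. Differences are log2(RPKM + 1) in a deletion library minus wild type, for the 9134 genes with a mean RPKM of at least 1 over all libraries (725 were removed). On this scale a pseudocount of 1 makes the difference of weakly expressed genes smaller. Genes at least 2-fold apart on that scale were counted. With 1 library per genotype there is no test across libraries and no p-value. Folds of named genes are ratios of RPKM with exact conditional (Clopper-Pearson) 95% intervals from the read counts. Where a library had 0 reads, the fold was computed against 3 reads in that library and is given as a lower bound. Shares of reads have 95% Wilson score intervals. Likeness between libraries is Pearson's and Spearman's correlation of log2(RPKM + 1) across genes, together with the median over genes of a chi-square statistic of the counts, relative to its value when libraries differ by counting error alone.

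Genes named in each comparison were the 6 highest and 6 lowest kept genes with an informative name and at least 10 RPKM in the higher library. The rule also took the 3 most different members of each list, the deleted genes and other conidiation regulators that the annotation names, the 10 named genes most clearly in the same direction in all deletions, and per library the 3 highest and 3 lowest named genes that stand apart. A gene stands apart when its log2(RPKM + 1) lies at least 1 above or below all other libraries. Genes outside the rule are said to have been chosen after their values were seen.

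23 gene lists were fixed as text patterns, searched in the annotation of the deposited table. They are conidiation regulators, conidial wall and pigment genes, cellulases, hemicellulases, amylolytic enzymes, pectinases, chitin and beta-1,3-glucan metabolism, secreted peptidases, secondary metabolism backbone enzymes, cytochrome P450, sugar transporters, nitrogen and amino acid uptake, ribosomal proteins, histones, DNA replication and cell cycle, heat shock proteins and chaperones, proteasome, mitochondrial respiration, glycolysis and fermentation, oxidative stress defence, ergosterol biosynthesis, lipases and cutinases, and transposable elements with mitochondrial transcripts. 21 lists had at least 5 kept members. For these the median difference, relative to the median of all kept genes, was ranked among 10000 random lists of the same size drawn within 10 bins of mean expression. A list is called lower or higher at a percentile of at most 2.5 or at least 97.5. The last pattern matched 28 genes named for ribosomal RNA and 3 others, so it is described as ribosomal RNA processing. The cellulase pattern also took 5 genes of beta-1,3-glucan breakdown. The sugar transporter pattern did not take genes named sugar:H+ symporter, such as PDE_03140 and PDE_00197. The pattern for secreted peptidases matched names only, without regard to secretion, and took a methionyl aminopeptidase (PDE_07815).

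Alternatives planned were pseudocounts of 0.1 and 5, no filter on low values, a filter at a mean RPKM of 5, scaling by median-of-ratios factors, the median of the other 9 libraries as reference in place of wild type, random lists not matched on expression, and Spearman's correlation. Alternatives added after seeing the data were leaving out the flbA library or the libraries labelled flbD and abaA deletion from the shared sets, counting only genes whose 95% interval lies beyond 2-fold, leaving the genes PDE_06605 and PDE_06607 out of the totals, and narrowing the cellulase and ribosomal protein lists. All comparisons use the same wild-type library. Shared counts are therefore set beside a simulation in which counting error is the only source of difference and the wild-type library is shared, and beside the product expected of independent lists.

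The procedure was tested on simulated data with the depths of the 9 comparisons. Simulated 8-fold differences passed 2-fold for 96 to 100% of genes and 2.83-fold differences for 87 to 94%, while 0.739 to 1.82% of unchanged genes passed. The simulated libraries shared an expression profile and differed otherwise by counting error only. These shares therefore do not give the rate of false calls between single cultures. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. No count model across replicates was fitted, because none can be estimated from single libraries. Coverage percentages were used only to examine deleted genes and for the counts given among the additional observations. Raw reads were not analysed here, and a table of locus tags from another assembly of the species was not used here.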

Results

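Messenger RNA of Penicillium oxalicum, a soil mould that secretes plant cell wall-degrading enzymes, was counted in mycelia of the wild type and of 9 strains labelled as deletions of sporulation genes. In Aspergillus and related moulds the products of flbA, flbB, flbC, flbD and flbE act upstream of BrlA, the central activator of conidiation. AbaA and WetA act after BrlA, and StuA shapes the conidiophore. The name Swi6 is borne by unrelated proteins of budding and fission yeast, and the labels do not say which is meant. Each genotype is 1 library. Their depths were 5.15 megareads in wild type, 3.10 in the flbA, 6.89 in the flbB, 4.44 in the flbC, 7.60 in the flbD, 7.26 in the flbE, 6.61 in the wetA, 7.04 in the abaA, 7.11 in the stuA and 5.61 in the swi6 deletion library. There are no replicates, so no value below has a replicate error. Ranges in parentheses after a fold are 95% counting intervals, which cover counting error only and not the spread between cultures. Of 9859 genes, 9134 passed the expression filter. Simulated libraries that differ only by counting error gave 77 to 170 genes past 2-fold in the 9 comparisons.

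The levels of the deleted genes were read first, where the annotation names them. A gene named SOK2 (PDE_04095), of the APSES family of transcription factors to which StuA belongs, had 377 RPKM in wild type and 1 read in the stuA deletion library, where it was 5140.4-fold lower (922 to 203089). A gene named chromobox protein 1 (PDE_08896), of the chromodomain family to which fission yeast Swi6 belongs, had 43.9 RPKM in wild type and 1 read in the swi6 deletion library, where it was 179-fold lower (31.6 to 7097). Both pairings with a deletion were made by protein family after the values were seen. The gene named FlbD (PDE_03008) had 341 RPKM in wild type and 327 RPKM in the library labelled flbD deletion, from 2375 reads that covered 99.9% of its length. A gene named transcriptional enhancer factor (PDE_02932), of the TEA family of AbaA and paired with it after its values were seen, had 28.5 RPKM in wild type and 59.1 RPKM in the library labelled abaA deletion, from 993 reads over 99.8% of its length. These values go against the labels of those libraries, so directions given for them below hold for the libraries as labelled only. No gene is named flbA, flbB, flbC, flbE or wetA, so the loss of these genes could not be read by name. A search outside the planned comparisons took genes with at most 2 reads in 1 library and at least 30 in every other. It found only PDE_04095 in the stuA and only PDE_08896 in the swi6 deletion library. There were 50 in the flbA deletion library, 2 in wild type and 0 in the flbB, flbC, flbD, flbE, wetA and abaA libraries. A deleted gene with fewer reads elsewhere would be missed.

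BrlA itself (PDE_00087) was lower than in wild type (248 RPKM) in all 9 deletion libraries. It had 1 read in the flbA deletion library (996-fold lower, interval 179 to 39381) and was 190.2-fold lower (109 to 369) in the stuA and 139-fold lower (80.8 to 261) in the swi6 deletion library. Elsewhere it had 70.8 to 107 RPKM, a range that turned above the reference in the abaA, flbC, flbD and wetA libraries when the median of the other 9 libraries replaced wild type. A gene lower than wild type in all 9 deletion libraries must turn in those nearest to wild type, so this turn decides nothing. The FlbD-named gene, a Myb-type regulator, was lowest in the stuA (8.23 RPKM) and flbA (27.6 RPKM) deletion libraries and highest in the wetA deletion library (524 RPKM). A further gene named BrlA (PDE_00079) had at most 5 reads in any library. The list of conidiation regulators has only these 3 members.

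**Figure D1:**
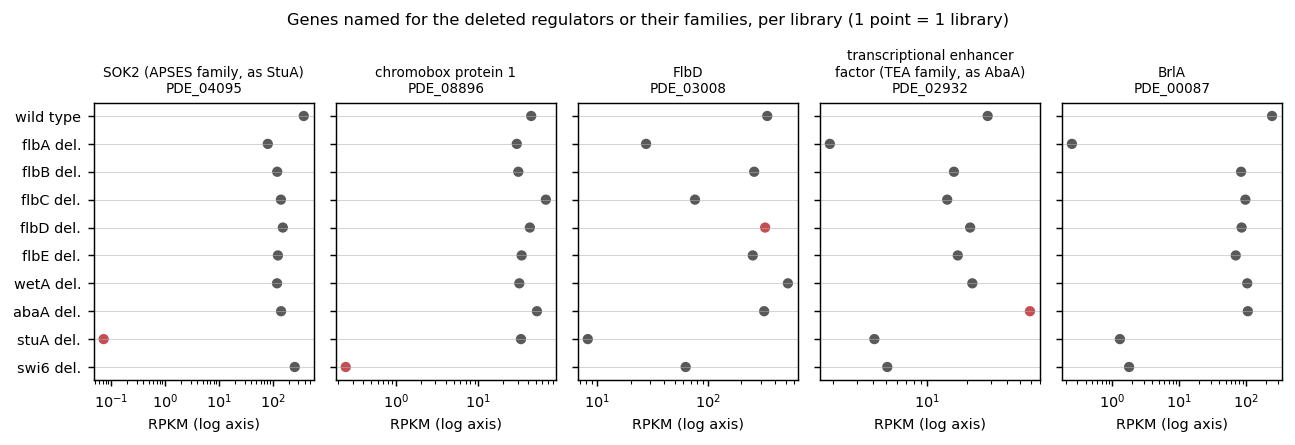
RPKM (log axis) of 5 regulator genes in each of the 10 libraries, 1 point per library, with the library labelled for the deletion of that gene or of a gene of its family in red. SOK2 and chromobox protein 1 stand at 0.0733 and 0.246 RPKM in those libraries, while the gene named FlbD and the TEA-family gene stand at 327 and 59.1 RPKM.

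The 4 genes listed for conidial pigment and the polyketide synthase PDE_09237 had lower RPKM than in wild type in every deletion library, by less than 2-fold for PDE_09491 in the library labelled flbD deletion. A gene named scytalone dehydratase (PDE_09236), after an enzyme of melanin synthesis, had 865 RPKM in wild type, 110.2 RPKM in the flbC and 21.7 RPKM in the swi6 deletion library, and at most 1 read in each of the other 7. A gene named tetrahydroxynaphthalene reductase (PDE_09239), after an enzyme of the same pathway, had 651 RPKM in wild type, 109.7 RPKM in the flbC, 26.4 RPKM in the swi6 and at most 3.21 RPKM in each other deletion library. PDE_09237, named monodictyphenone polyketide synthase, had 204 RPKM in wild type, 27.5 RPKM in the flbC and 5.92 RPKM in the swi6 deletion library. Its locus number lies between those of PDE_09236 and PDE_09239. Whether these genes serve melanin or another product was not tested. A second scytalone dehydratase (PDE_04496) had 417 RPKM in wild type, 0 reads in the flbA, 1.10 RPKM in the stuA and 5.91 RPKM in the swi6 deletion library, and 46.5 to 195 RPKM elsewhere. The naphtho-gamma-pyrone synthase PDE_09491 had 49.2 RPKM in wild type and 0.263 (stuA) to 31.7 RPKM (labelled flbD) in the deletion libraries. No hydrophobin was named in the annotation, so the list of conidial wall and pigment genes holds 4 genes, too few to be ranked against random lists. From the median of the other 9 libraries in place of wild type, PDE_09236, PDE_09237 and PDE_09239 turned to higher in the flbC (by 6.80, 4.66 and 5.39 on the log2 scale) and swi6 (by 4.51, 2.61 and 3.38) deletion libraries, and each of the 5 genes turned in at least 1 further library. Such turns follow by construction for genes lower than wild type in every deletion library, and only their size is informative.

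204 genes were at least 2-fold lower and 117 at least 2-fold higher than wild type in all 9 deletion libraries. Among those lower were an alpha-1,3-glucanase of cell wall breakdown (PDE_06621, 979 RPKM in wild type against 0 to 9.33), a cytochrome P450 (PDE_00811, 74.0 against 0 to 2.71), an ornithine decarboxylase of polyamine synthesis (PDE_04039, 59.9 against 0 to 4.54) and an acetyl-CoA synthetase (PDE_01716, 22.2 against 0 to 1.75). Also lower were a 3-dehydroquinate synthase of the shikimate pathway (PDE_00008, 473 against 1.14 to 63.7) and an alpha-glucosidase (PDE_02648, 34.2 against 0 to 3.90). Those higher included a nitric oxide dioxygenase, which detoxifies nitric oxide (PDE_01345, 15.4 RPKM against 300.3 to 8676), and a small heat shock protein of the HSP20 family (PDE_00322, 28.8 against 279.8 to 4991). At 4-fold the shared counts were 85 lower and 34 higher. Counting error with a shared wild-type library gave 0 lower and 6 higher genes in simulation, and independent lists would share 0.000839 and 6.16e-05. The single wild-type library enters all 9 differences and cannot be split, so part of the shared set may come from that library. The median of the other 9 libraries as reference cannot decide this. A gene on the same side of wild type in all 9 deletions must turn direction against it in the deletion libraries nearest to wild type. PDE_06621, PDE_02648, PDE_01345 and PDE_00322 turned in this way in 1 or more deletion libraries, and not every gene was tried in every library. The shared higher count became 214 without the flbA deletion library and 187 with median-of-ratios scaling.

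The libraries labelled flbB, flbD, flbE, wetA and abaA deletion were close to each other. Their 10 pairs had correlations across genes of 0.947 to 0.982 and 236 to 1045 genes 2-fold apart. Among the 25 pairs of these libraries with the remaining 5, correlations were 0.720 to 0.867 with 1876 to 4575 genes apart. Genes are not independent replicates, so these correlations carry no test. Wild type differed from every deletion library by 2093 to 4315 genes. The genes that set a library apart from all 9 others were few in the close libraries, with 7 above and 1 below for the library labelled flbD deletion, against 191 above and 1260 below for the flbA deletion library. A catechol dioxygenase of aromatic compound breakdown (PDE_07946, 112.5 RPKM) stood highest in the library labelled flbD deletion, and the TEA-family gene in the library labelled abaA deletion.

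**Figure D2:**
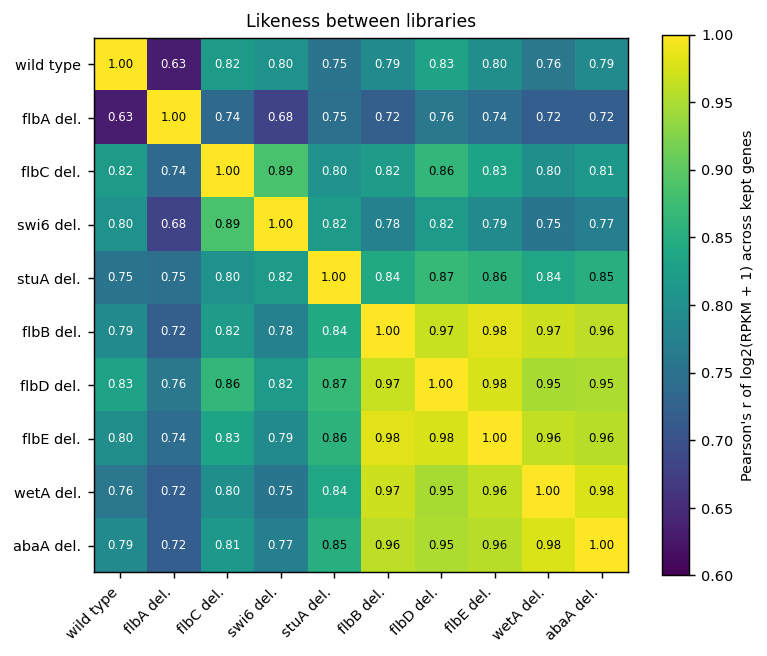
Pearson's r of log2(RPKM + 1) across 9134 kept genes for each pair of the 10 libraries, as a colour scale with the value in each cell. The libraries labelled flbB, flbD, flbE, wetA and abaA deletion form a block at 0.95 to 0.98, and the lowest value is 0.63 between wild type and the flbA deletion library.

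The flbA deletion asks what the regulator of G-protein signalling FlbA controls. Among its highest named genes, a zinc transporter (PDE_06461) with 0 reads in wild type had 1800.2 RPKM, at least 3347-fold higher. A superoxide dismutase (PDE_00326) was 611-fold higher (391 to 1015), and copper transporters were 689.7-fold higher (316 to 1881) for PDE_05901 and 298-fold higher (193 to 488) for PDE_05328. Nitrate reductase (PDE_00369) was at least 820.0-fold higher, nitrite reductase (PDE_00370) 1409-fold higher (603 to 4341) and a nitrate transporter (PDE_00371) 48.1-fold higher (33.4 to 71.7), and these 3 genes carry consecutive locus numbers. A sugar symporter (PDE_03140) was 621-fold higher (376 to 1109.5). Chitinase PDE_08122, which breaks down wall chitin and had 24408 RPKM in wild type, was 1039-fold lower (849 to 1286). Also among its lowest named genes were the alpha-1,3-glucanase PDE_06621 at least 2052-fold lower, the beta-1,3-glucanase PDE_05515 808-fold lower (452 to 1619.6) and scytalone dehydratase PDE_09236 at least 469.7-fold lower. A salicylate synthetase (PDE_03182) had 1 read against 866 RPKM in wild type, 3571-fold lower (641 to 141083).

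By list, the flbA deletion library was lower for amylolytic enzymes (median -1.91, percentile 0.0600), with Amy13A (PDE_01201) 241-fold lower (169 to 357) and glucoamylase Amy15A (PDE_09417) 74.8-fold lower (63.1 to 89.5). It was also lower for pectinases (median -1.37, percentile 0.180), where a rhamnogalacturonan hydrolase (PDE_09285) was 121-fold lower (72.1 to 222), for hemicellulases (median -0.61, percentile 0.690), for chitin and beta-1,3-glucan genes (median -0.32, percentile 2.12) and for secondary metabolism backbone enzymes (median -2.38, percentile 0.0200). The chitin list was split, with 16 of 71 members at least 2-fold above and 25 below the median gene, and its call ended under every alternative tried. Medians are log2 differences relative to the median of all genes. Within hemicellulases an endoglucanase (PDE_02886) went the other way, 57.2-fold higher (31.6 to 116). Higher lists were mitochondrial respiration (median 1.15, percentile 100), oxidative stress defence (median 1.44, percentile 100), ribosomal proteins (median 0.95, percentile 100), ergosterol biosynthesis (median 1.03, percentile 99.99), nitrogen and amino acid uptake (median 0.95, percentile 99.95), heat shock proteins (median 0.63, percentile 98.2) and ribosomal RNA processing (median 0.46, percentile 97.7). A cytochrome c oxidase assembly protein (PDE_08885) was 16.6-fold higher (14.1 to 19.7), the Hsp70-type protein PDE_02379 15.9-fold higher (15.4 to 16.4) and thioredoxin reductase (PDE_08354) 9.20-fold higher (7.79 to 10.9). Sterol demethylase PDE_09230, a member of the ergosterol list, went against it, with 93.3 RPKM in wild type and 0 reads here. Its locus number lies in a run of 5 genes from PDE_09229 that were lower than wild type in all 9 deletion libraries. Whether it serves ergosterol synthesis was not tested.

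In the flbA deletion library 895 genes were higher and 3420 lower, 4315 in total, with a median shift of -0.64 over all genes. Scaling by median-of-ratios gave 1865 higher and 2112 lower, and 2849 genes had an interval beyond 2-fold. The unnamed gene PDE_06605, chosen after its values were seen, took 27.9% (27.8 to 27.9) of this library's reads against 7.73% (7.71 to 7.76) in wild type. Leaving that gene out of the totals moved the median shift of this library from -0.64 to -0.32. 946 genes had 0 reads here, against 440 in wild type and 557 after wild type was thinned to this depth. The thinning matched the read total only. With the larger share of PDE_06605, fewer reads were left for other genes here than in the thinned wild type. With the median of the other 9 libraries as reference 7 of the 12 list calls were not met, and the ribosomal RNA processing median changed sign.

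**Figure D3:**
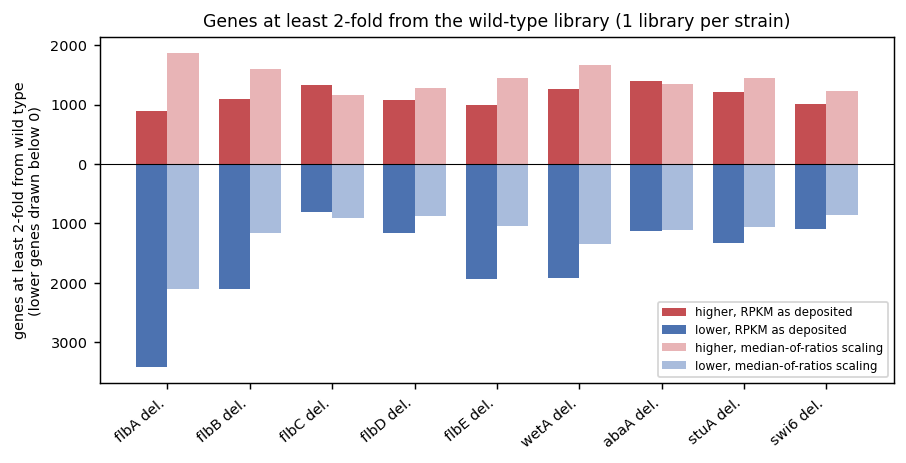
Genes at least 2-fold higher (above 0) or lower (drawn below 0) than the wild-type library in each deletion library, 1 library per strain, with RPKM as deposited and after median-of-ratios scaling. The flbA deletion bars run from 895 higher and 3420 lower to 1865 higher and 2112 lower after scaling.

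The flbB deletion asks what a bZIP-type regulator of early conidiation controls. Among its highest named genes, the nitric oxide dioxygenase PDE_01345 was 409.9-fold higher (337 to 504), a sodium-exporting ATPase (PDE_03497) 253-fold higher (209.6 to 309), a sugar symporter (PDE_00197) 317-fold higher (211 to 501) and the disaggregase ClpB (PDE_00624), which rescues aggregated proteins, 169-fold higher (148 to 193). A norsolorinic acid ketoreductase-like gene (PDE_04277) was 176-fold higher (105 to 322) and a zinc finger gene (PDE_07902) 43.2-fold higher (39.4 to 47.4). Besides PDE_09236, PDE_09237 and PDE_09239, chitinase PDE_01168 was 403-fold lower (212 to 882) and the secreted aspartic protease aspergillopepsin (PDE_07927) 202-fold lower (149 to 279.9). Hydrolase lists were lower, namely cellulases (median -0.52, percentile 0.940), hemicellulases (median -0.62, percentile 0.0300), amylolytic enzymes (median -0.90, percentile 0), pectinases (median -0.77, percentile 0.580), secreted peptidases (median -0.50, percentile 0.300) and chitin and beta-1,3-glucan genes (median -0.26, percentile 0.270). Glucoamylase Amy15A (PDE_09417) was 14.9-fold lower (14.1 to 15.7) and a tripeptidyl peptidase (PDE_01353) 8.57-fold lower (7.29 to 10.1). DNA replication genes were lower as a list (median -0.46, percentile 0.0800), with the replication clamp PCNA (PDE_02943) 3.85-fold lower (3.05 to 4.89) and the helicase subunit MCM5 (PDE_09895) 3.65-fold lower (3.05 to 4.40). Proteasome genes (median -0.15, percentile 0.610) were called lower and ribosomal RNA processing genes (median 0.98, percentile 100) higher. Ribosomal proteins were called lower at percentile 0 with a median of -0.03 and a mean of 0.08, since similarly abundant genes had higher medians. Counts were 1099 higher and 2103 lower (total 3202, or 2028 by an interval beyond 2-fold, shift -0.40), and 1596 higher and 1163 lower after median-of-ratios scaling. Taking the median of the other 9 libraries as reference, 725 genes were 2-fold apart and 7 of the 10 list calls were not met, among them cellulases, whose call also ended without the 5 beta-1,3-glucan genes (percentile 17.3).

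The library labelled flbD deletion, in which the FlbD-named gene was at wild-type level, asks about a Myb-type regulator. Here the nitric oxide dioxygenase PDE_01345 was 231-fold higher (189.6 to 284), ClpB (PDE_00624) 113-fold higher (99.3 to 129), the sodium ATPase PDE_03497 82.4-fold higher (68.2 to 101) and a RING-type gene (PDE_09658) 32.8-fold higher (26.6 to 40.8). Hydroxyphenylpyruvate dioxygenase (PDE_09761), which breaks down tyrosine, was 111-fold lower (88.0 to 142), and chitinase PDE_01168 was 182-fold lower (119.8 to 291). Lower lists were cellulases (median -0.46, percentile 0.5), hemicellulases (median -0.48, percentile 0.0450), amylolytic enzymes (median -0.80, percentile 0), pectinases (median -0.61, percentile 0.910), chitin and beta-1,3-glucan genes (median -0.24, percentile 0.140), secreted peptidases (median -0.32, percentile 0.590) and proteasome (median -0.13, percentile 0.220). The cellulase call ended without the 5 beta-1,3-glucan genes. Cellulose monooxygenase Cel61A (PDE_05633) had 0 reads against 12.9 RPKM in wild type. Higher lists were nitrogen and amino acid uptake (median 0.45, percentile 99.05), ergosterol biosynthesis (median 0.43, percentile 97.6) and ribosomal RNA processing (median 0.80, percentile 100). An amino acid transporter (PDE_00845) was 11.6-fold higher (10.9 to 12.3) and the ribosomal RNA methyltransferase fibrillarin (PDE_00286) 2.51-fold higher (2.29 to 2.76). Counts were 1072 higher and 1157 lower (total 2229, or 1438 by an interval beyond 2-fold, shift -0.20), and 1283 higher and 878 lower after median-of-ratios scaling. Against the median of the other 9 libraries, 463 genes were 2-fold apart, 7 of the 10 list calls were not met, and the ergosterol list moved to the other side of random lists.

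The flbE deletion asks about a partner of FlbB at the hyphal tip. The nitric oxide dioxygenase PDE_01345 reached 8676 RPKM (564-fold higher, interval 464 to 694), ClpB (PDE_00624) was 175-fold higher (154 to 200.2), the sugar symporter PDE_00197 301-fold higher (200.4 to 475) and fructose-bisphosphatase (PDE_08481), an enzyme of gluconeogenesis, 39.7-fold higher (33.7 to 47.2). Aspergillopepsin (PDE_07927) was 198-fold lower (148 to 272) and hydroxyphenylpyruvate dioxygenase (PDE_09761) 258-fold lower (180.4 to 382). Peptidases listed as secreted by name were lower as a list (median -0.58, percentile 0.0100). This list also held a methionyl aminopeptidase (PDE_07815), at 48.4 RPKM against 119 in wild type, and secretion was not checked. Lower too were hemicellulases (median -0.57, percentile 0.0600), amylolytic enzymes (median -0.82, percentile 0.0100), chitin and beta-1,3-glucan genes (median -0.16, percentile 2.27), DNA replication genes (median -0.43, percentile 0.0400) and proteasome genes (median -0.17, percentile 0.180). A tripeptidyl peptidase (PDE_01353) was 13.5-fold lower (11.1 to 16.5) and a replication factor C subunit (PDE_01938) 3.601-fold lower (2.63 to 4.997). Nitrogen uptake (median 0.52, percentile 99.2) and ribosomal RNA processing (median 0.70, percentile 99.98) were higher, although an oligopeptide transporter (PDE_05534) was 59.1-fold lower (41.0 to 88.7). Ribosomal proteins had a median of 0.03 at percentile 0.02, a call that turned to the other side against random lists not matched on expression. Counts were 993 higher and 1940 lower (total 2933, or 1832 by an interval beyond 2-fold, shift -0.40), and 1449 higher and 1047 lower after median-of-ratios scaling. When the median of the other 9 libraries was the reference, 578 genes were 2-fold apart, 5 of the 9 list calls were not met, and the amylolytic median changed sign.

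The wetA deletion asks about a regulator of spore maturation. The sodium ATPase PDE_03497 was 279.7-fold higher (232 to 341), the ketoreductase-like gene PDE_04277 234-fold higher (139 to 429), ClpB (PDE_00624) 161-fold higher (141 to 184) and the zinc finger gene PDE_07902 47.5-fold higher (43.4 to 52.2). The nitric oxide dioxygenase PDE_01345 was 32.4-fold higher (26.6 to 39.96), well under its level in the flbE deletion library. Chitinase PDE_01168 was 696-fold lower (298 to 2145) and glucoamylase Amy15A (PDE_09417) 98.7-fold lower (86.2 to 113). Amylolytic enzymes (median -1.31, percentile 0), pectinases (median -0.90, percentile 0.410), hemicellulases (median -0.65, percentile 0.05), secreted peptidases (median -0.62, percentile 0.130), chitin and beta-1,3-glucan genes (median -0.25, percentile 0.960), DNA replication genes (median -0.41, percentile 0.430) and proteasome genes (median -0.26, percentile 0.140) were lower. An alpha-glucosidase (PDE_03966) was 25.6-fold lower (22.8 to 28.9) and PCNA (PDE_02943) 4.52-fold lower (3.52 to 5.86). Nitrogen uptake (median 0.57, percentile 99.4), ergosterol biosynthesis (median 0.57, percentile 98.5) and ribosomal RNA processing (median 0.94, percentile 100) were higher. Hydroxymethylglutaryl-CoA lyase (PDE_04619), which the pattern of the ergosterol list took although it acts in leucine breakdown, was 8.29-fold higher (6.48 to 10.8). Ribosomal proteins had a median of 0.03 at percentile 0.56, which likewise turned against unmatched random lists. Counts were 1258 higher and 1912 lower (total 3170, shift -0.26), and 1657 higher and 1345 lower after median-of-ratios scaling. Measured from the median of the other 9 libraries, 1005 genes were 2-fold apart and 5 of the 11 list calls were not met.

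The library labelled abaA deletion, in which the TEA-family gene was above its wild-type level, asks about a regulator of the spore-forming cell. The sodium ATPase PDE_03497 was 225-fold higher (187 to 275), ClpB (PDE_00624) 121-fold higher (106 to 138) and a chitinase (PDE_01573) 37.2-fold higher (29.6 to 47.4), whereas chitinase PDE_01168 was 412-fold lower (216 to 901). Aspergillopepsin (PDE_07927) was 180.1-fold lower (136 to 245) and glucoamylase Amy15A (PDE_09417) 40.2-fold lower (36.9 to 43.8). Hemicellulases (median -0.55, percentile 0.0400), amylolytic enzymes (median -0.89, percentile 0.0200), chitin and beta-1,3-glucan genes (median -0.29, percentile 0.140), secreted peptidases (median -0.60, percentile 0.110) and DNA replication genes (median -0.37, percentile 0.0850) were lower. Among genes taken by the hemicellulase pattern, an endoxylanase (PDE_02101) was 7.65-fold lower (4.97 to 12.2). An alpha-1,6-mannanase (PDE_00051), taken for the word mannanase in its name, was 16.8-fold higher (14.0 to 20.3), against the list. Whether that gene acts on hemicellulose was not tested. Nitrogen uptake (median 0.39, percentile 98.2) and ribosomal RNA processing (median 0.79, percentile 100) were higher, with allantoinase (PDE_04944), which degrades purines, 8.11-fold higher (6.36 to 10.5). Counts were 1388 higher and 1121 lower (total 2509, shift 0.03). From the median of the other 9 libraries 858 genes were 2-fold apart, none of the 7 list calls was met, and the nitrogen uptake median changed sign.

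The flbC deletion asks about a zinc finger regulator of early conidiation. A gene named 1,3-beta-glucan synthase (PDE_07868) had 2.17 RPKM in wild type and 1515 RPKM here, 698-fold higher (321 to 1904). Its 3615 reads at that RPKM imply a short coding region, so the name may cover only part of an enzyme, and its function was not tested. A glutathione S-transferase (PDE_01194) was 179-fold higher (104 to 336), a chitin-binding protein (PDE_03292) 111-fold higher (68.4 to 196) and an amino acid transporter (PDE_00830) 130.2-fold higher (75.9 to 245). Methylisocitrate lyase (PDE_06062), of propionate breakdown, was 202-fold lower (169 to 243), a peptide transporter (PDE_06899) 209-fold lower (142 to 319), a cutinase (PDE_07475) 146-fold lower (109 to 199) and the salicylate synthetase PDE_03182 426-fold lower (244 to 825). Higher lists were oxidative stress defence (median 0.51, percentile 99.9), ergosterol biosynthesis (median 0.44, percentile 99.7), mitochondrial respiration (median 0.31, percentile 99.7), heat shock proteins (median 0.39, percentile 99.7), nitrogen uptake (median 0.38, percentile 99.1) and ribosomal RNA processing (median 0.68, percentile 100). A methylsterol monooxygenase (PDE_05808) was 9.14-fold higher (8.06 to 10.4) and the HSP20-family gene PDE_09235 15.0-fold higher (13.6 to 16.6). The latter had 421 reads in wild type, 5453 in the flbC and 778 in the swi6 deletion library, and 0 to 2 in the other 7 deletion libraries. Lower lists were hemicellulases (median -0.51, percentile 0), amylolytic enzymes (median -0.60, percentile 0.280), chitin and beta-1,3-glucan genes (median -0.36, percentile 0), cellulases (median -0.37, percentile 1.05) and secondary metabolism backbone enzymes (median -0.77, percentile 1.14), with an alpha-glucosidase (PDE_00400) 26.5-fold lower (23.8 to 29.6). Without the 5 beta-1,3-glucan genes cellulases were no longer called here. Counts were 1337 higher and 808 lower (total 2145, shift 0.12), and 133 genes stood above all other libraries. 1366 genes had an interval beyond 2-fold. Set against the median of the other 9 libraries, 6 of the 11 list calls were not met, and the amylolytic, secondary metabolism, nitrogen uptake and ribosomal RNA medians changed sign.

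The stuA deletion asks about an APSES-family regulator. Among its highest named genes were a chitinase (PDE_01573) 446-fold higher (356 to 567), an endoxylanase (PDE_05210) 217-fold higher (121 to 436) and a chitosanase (PDE_01255) 57.3-fold higher (37.0 to 94.1). Chitinase PDE_01168, much lower in several other deletion libraries, stood above all other libraries here, at 14039 RPKM against 528 in wild type. The list of chitin and beta-1,3-glucan genes was not called (median 0.042, percentile 47.2), with 15 of 71 members at least 2-fold above and 17 below the median gene, and was called higher with the median of the other 9 libraries as reference (median 0.25, percentile 99.85). The small heat shock gene PDE_00322 was 173-fold higher (149 to 203), the sugar symporter PDE_03140 208-fold higher (126 to 372) and the glutathione S-transferase PDE_01194 124-fold higher (72.3 to 233). Hemicellulases (median 0.24, percentile 99.3) and cellulases (median 0.39, percentile 99.1) were higher as lists here, and lower where called against wild type in other deletion libraries. The endoglucanase PDE_02886 was 33.7-fold higher (18.7 to 67.9). The pattern for sugar transporters did not take the sugar symporter PDE_03140. Its list of 5 genes was called higher (median 1.22, percentile 99.4), with 3 members at least 2-fold higher and 1 at least 2-fold lower. The higher ones were cellodextrin transporters, which import cellulose breakdown products, among them CdtC (PDE_00607, 8.36-fold higher, interval 7.04 to 9.9998) and CdtD (PDE_00753, 2.12-fold higher, interval 1.90 to 2.38), and the lower one a UDP-sugar transporter (PDE_04161, 42.2 RPKM in wild type and 20.5 here). A pectate lyase (PDE_06068, 18.2-fold higher, interval 16.2 to 20.6) and a polygalacturonase (PDE_03218, 36.6-fold higher, interval 29.3 to 46.1), both chosen after their values were seen, were higher too, while the pectinase list was not called (median 0.35, percentile 96.9). It was called higher with a filter at a mean RPKM of 5 (median 0.47, percentile 97.8) and with the median of the other 9 libraries as reference (median 0.83, percentile 99.99). Oxidative stress defence (median 0.90, percentile 100), nitrogen uptake (median 0.63, percentile 99.9) and ribosomal RNA processing (median 0.76, percentile 100) were higher. Amylolytic enzymes (median -0.68, percentile 0.160) were lower, with the alpha-glucosidase PDE_00400 3.48-fold lower (3.36 to 3.61), and so were DNA replication genes (median -0.50, percentile 0), with thymidylate synthase (PDE_05716) 5.02-fold lower (3.20 to 8.16) and a cyclin-dependent kinase (PDE_08919) 3.15-fold lower (2.74 to 3.62). A gene named tyrosinase (PDE_04260), with a coding length of only 309 bases, had 0 reads against 395 RPKM in wild type, at least 289-fold lower. Counts were 1217 higher and 1334 lower (total 2551, or 1696 by an interval beyond 2-fold, shift -0.15), and 1443 higher and 1066 lower after median-of-ratios scaling. Judged from the median of the other 9 libraries, 1690 genes were 2-fold apart, 6 of the 8 list calls kept their side, and the amylolytic median changed sign.

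The swi6 deletion asks about a regulator whose kind the labels leave open. Among the 21 lists with at least 5 kept members, ribosomal proteins were farthest from wild type (median -2.11, percentile 0), with 76 of 122 members at least 2-fold lower. The 79 members named as the cytosolic type had a median of -2.33 (quartiles -2.51 and -2.17), and the 43 of the mitochondrial or bacterial type -0.23. Among the cytosolic ones S3e (PDE_02754) was 9.96-fold lower (8.58 to 11.6) and S20e (PDE_01695) 9.52-fold lower (7.94 to 11.5), while the mitochondrial YMR-31 (PDE_02554) was 17.0-fold higher (14.7 to 19.9). A formate dehydrogenase (PDE_01080), which oxidises formate, was 139-fold higher (128 to 151) and reached 13478 RPKM. An arabinofuranosidase (PDE_07585) was 135-fold higher (112 to 166), an aspergillopepsin (PDE_07344) 85.5-fold higher (64.4 to 116) and a lipase (PDE_06813) 54.1-fold higher (27.2 to 126). Lower were the cutinase PDE_07475 (604-fold lower, interval 359.8 to 1105), the peptide transporter PDE_06899 (244-fold lower, interval 169 to 368), a cyclic dipeptide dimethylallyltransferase, which prenylates alkaloid precursors (PDE_01066, 224-fold lower, interval 147 to 363) and methylisocitrate lyase PDE_06062 (164-fold lower, interval 142 to 190.2). Secondary metabolism backbone enzymes (median -0.93, percentile 0.540), amylolytic enzymes (median -0.73, percentile 0.0900) and proteasome genes (median -0.21, percentile 0.645) were lower. Oxidative stress defence (median 0.49, percentile 99.8) and nitrogen uptake (median 0.40, percentile 99.4) were higher. DNA replication genes, targets of the budding yeast Swi6 complexes, were not called (median 0.02, percentile 75.9) but were called higher with the median of the other 9 libraries as reference (median 0.40, percentile 99.98). Counts were 1003 higher and 1090 lower (total 2093, or 1364 by an interval beyond 2-fold, shift -0.14), and 1232 higher and 864 lower after median-of-ratios scaling. Under the median of the other 9 libraries as reference 5 of the 6 list calls were not met, the exception being ribosomal proteins, and the amylolytic, nitrogen uptake and proteasome medians changed sign.

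Across deletions, amylolytic enzymes were called lower in all 9 libraries and hemicellulases in 7. Nitrogen and amino acid uptake was called higher in all but the flbB deletion (percentile 85.4), and ribosomal RNA processing in all but the swi6 deletion (percentile 54.7). Heat shock proteins were called as a list in the flbA and flbC deletions. With random lists not matched on expression they were called higher also in the flbB (percentile 97.6), flbE (98.5), wetA (97.85) and abaA (98.95) deletions, and with the median of the other 9 libraries as reference higher in the flbD (99.9), lower in the abaA (0.670) and no longer in the flbC deletion. ClpB (PDE_00624) had 18.5 RPKM in wild type and 66.1 to 3236 RPKM in the deletion libraries, and the Hsp70-type gene PDE_02379 had 392 against 878 to 11056. Other members fell, with 15 of 40 at least 2-fold higher and 10 lower than wild type in the flbB deletion library. In the wetA deletion library 15 were higher and 11 lower. PDE_09235 fell from 421 reads to 0 to 2 in 7 deletion libraries. Its locus number lies next to that of PDE_09236, which had at most 1 read in the same 7 libraries. Its fall may therefore not speak for heat shock genes. Cytochrome P450 genes (percentiles 48.6 to 87.5), histones (4.87 to 81.5), glycolysis and fermentation (11.96 to 95.5) and lipases and cutinases (6.36 to 91.0) were called in no deletion against wild type with matched random lists. Cytochrome P450 genes and histones gained no call under any alternative. Glycolysis was called higher in the flbA deletion with unmatched random lists (98.4). With the median of the other 9 libraries as reference it was called higher in the flbC (98.4) and stuA (98.1) and lower in the wetA (2.30) and abaA (2.26) deletions, and lipases lower in the flbD deletion (2.46). All 5 proteasome calls and the ribosomal protein call in the flbB deletion ended against random lists not matched on expression. Cellulases in the flbB, flbD and stuA, hemicellulases in the flbA, flbE and stuA, pectinases in the flbD and wetA, chitin genes in the flbE and wetA, secreted peptidases in the flbB and flbD, nitrogen uptake in the flbC, abaA and swi6, ergosterol biosynthesis in the flbD and ribosomal RNA processing in the flbA deletion each lost their call under at least 1 other pseudocount, filter or set of random lists. Of 189 tests of a list in a deletion, 32 were called higher and 52 lower, where lists of unrelated genes would give 9.45. That number assumes that members of a list vary independently, which genes of a common function need not do. The tests also share the wild-type library, so the calls are not independent of each other.

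**Figure D4:**
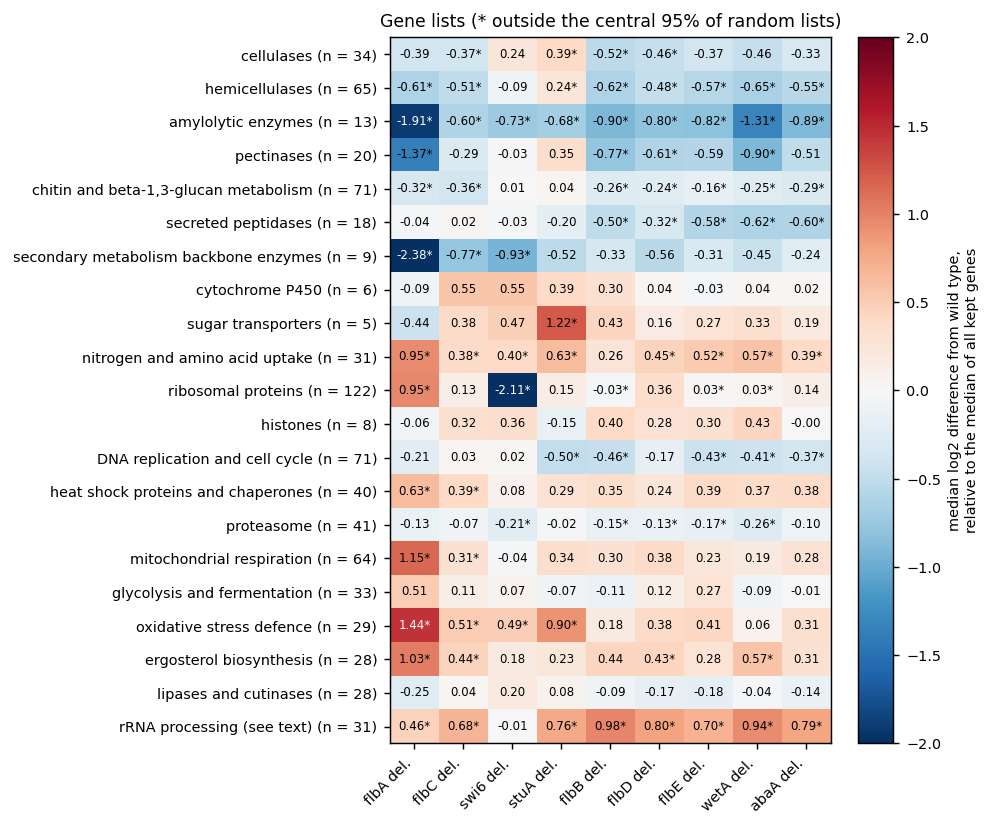
Median log2 difference from wild type, relative to the median of all kept genes, of 21 gene lists (lines) in 9 deletion libraries (columns), with n the kept members and an asterisk where the median lay outside the central 95% of random lists. Ribosomal proteins in the swi6 deletion (-2.11) and secondary metabolism enzymes in the flbA deletion (-2.38) are lowest, and oxidative stress defence in the flbA deletion (1.44) is highest.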

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

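The tests of carried genes, of remnants of deleted genes, of the wild-type state for heat shock proteins in the flbA and flbC deletions, of culture stress and of a few genes taking most counts were chosen only after the results were seen. Coverage percentages, a measurement outside the comparisons, showed genes read over at least 90% of their length in a deletion library and over at most 10% in wild type. There were 14 such genes in the flbA deletion library, 6 in the flbB, 13 in the flbC, 3 in the library labelled flbD deletion, 5 in the flbE, 10 in the wetA, 12 in the library labelled abaA deletion, 18 in the stuA and 11 in the swi6 deletion library. The reverse, genes covered in wild type and not in the deletion library, numbered 7 in the flbC to 220 in the flbA deletion library.

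The libraries labelled flbB, flbD, flbE, wetA and abaA deletion lay close together, and the genes named FlbD (PDE_03008) and transcriptional enhancer factor (PDE_02932) were read in the libraries labelled flbD and abaA deletion. A single library deposited several times is argued against. The smallest median chi-square of the counts over the 10 pairs was 4.60 times its value under counting error alone. Reads from a remnant of a partly deleted gene are also argued against, since coverage was 0 percentage points below wild type for the FlbD-named gene and 0.04 points below for the TEA-family gene. The RPKM at 95.7% and 207% of wild type are consistent with both libraries coming from cells that carry these genes, which a mixed-up sample, or the deletion of a gene that the annotation names otherwise, could give. A shared response to deletions in 1 pathway stays open for the likeness of the 5 libraries and was not tested.

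Heat shock proteins were called higher as a list in the flbA and flbC deletions against wild type with matched random lists, while unmatched random lists added higher calls in flbB, flbE, wetA and abaA, and the median of the other 9 libraries as reference added a higher call in flbD and a lower one in abaA and ended that in flbC. A state of the wild-type library alone cannot be told apart from an effect of the deletion in either, because the members of the list went both ways against the median of the other 8 deletion libraries, at a median of 0.43, quartiles of -0.27 and 0.98 and percentile 98.6 of random lists in the flbA and a median of -0.13, quartiles of -1.18 and 0.32 and percentile 49.5 in the flbC deletion. The flbE minus the swi6 deletion library (percentile 78.5) decides nothing, as the list was called in neither. Stress of single cultures at growth or harvest cannot be told apart from an effect of the deletion either, because each genotype is 1 culture, with 18 members at least 2-fold above and 6 below the median gene in the flbA deletion library and 10 above and 3 below in the flbC. The deletions themselves remain a possible explanation that was not tested further.

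Ribosomal proteins were lower in the swi6 deletion library, with a median of -2.11 over 122 genes. A loss of short transcripts is argued against, as the median lay at percentile 0 of random lists matched on length, the lowest of which had -0.26. A loss or compression of abundant transcripts is argued against in the same way, at percentile 0 of lists matched on the wild-type level, the lowest of which had -0.61. A few genes taking most of the counts would move all genes alike, and the median of -2.11 is relative to the median gene. An effect of the deletion on cytosolic ribosomal protein genes may therefore be held as a hypothesis, found and tested on the same single library, with the growth state of that culture left untested.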

How the results depend on the processing

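With 1 library per genotype no alternative can show how far cultures of the same strain differ, and depth limits the flbA deletion library most, where 3 reads on a gene of 1 kilobase are worth 0.967 RPKM. No paired analysis was possible because each genotype has 1 library. Of the counts of genes at 2-fold from wild type, 58 kept within 1.5 times the reported value and 14 moved. Of the counts of genes that stand apart, 39 kept and 11 moved. The 84 calls of single lists kept direction and call 504 times over the alternatives, kept direction without the call 79 times, and turned 14 times. Differences of named genes kept 1799 times, moved 770 times and turned 59 times. Kept means within the counting interval, or within a fixed log2 margin for genes that were shared or stood apart. Using no filter or a filter at a mean RPKM of 5 cannot change a gene's own difference. The 454 and 440 results kept under these settings were therefore fixed in advance and show nothing. Every turn was with the median of the other 9 libraries as reference. That reference leaves out what all deletion libraries share, so by its construction it removes shared differences, and for all other changes the cause was not tested. Median-of-ratios scaling turned no gene and no list, which follows nearly by construction. It moves all genes of a library by almost the same amount, so a list ranked among them can hardly turn. With it 83 of the 84 list calls were kept. For genes a turn was counted only from a 2-fold difference, so a smaller shift could not show as a turn.

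Counting only genes whose 95% interval lies beyond 2-fold, an alternative chosen after seeing the data, gave 2849 genes for the flbA, 2028 for the flbB, 1366 for the flbC, 1438 for the flbD, 1832 for the flbE, 1696 for the stuA and 1364 for the swi6 deletion. With a pseudocount of 5 the flbE deletion gave 1938. With the median of the other 9 libraries as reference the counts were 725 for flbB, 463 for flbD, 578 for flbE, 1005 for wetA, 858 for abaA and 1690 for stuA. Genes higher in all deletions numbered 187 with median-of-ratios scaling, and 214 without the flbA deletion library, an alternative chosen after seeing the data. Leaving the genes PDE_06605 and PDE_06607 out of the totals, also chosen after seeing the data, kept all 9 counts within 1.5 times, as leaving out the libraries labelled flbD and abaA deletion did for both shared sets.

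Genes standing apart numbered 874 in the flbA deletion library with a pseudocount of 5, where flbB had 3, flbE 2, wetA 8 and abaA 7. With a pseudocount of 0.1 they numbered 20 in flbB, 21 in flbD, 15 in flbE and 43 in wetA, and with median-of-ratios scaling 8 in flbB and 8 in flbE. By Spearman's correlation the lowest value among the 5 close libraries was 0.944 and the highest of wild type with a deletion library 0.841. Called lists numbered 5 for flbA, 6 for flbB, 5 for flbE and 4 for abaA with the median of the other 9 libraries as reference, of which 5, 3, 4 and 0 in that order were called on the same side against wild type. Against random lists not matched on expression abaA had 11.

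Lists not called against wild type gained a call 60 times, 33 of them with the median of the other 9 libraries as reference, 18 against unmatched random lists, 3 with a filter at a mean RPKM of 5, 2 with no filter, 2 without the mitochondrial ribosomal proteins and 1 with each other pseudocount. With that reference the swi6 deletion gained higher cellulases, hemicellulases, pectinases, chitin genes, secreted peptidases and DNA replication and lower mitochondrial respiration and ribosomal RNA processing. The flbC deletion gained higher secreted peptidases, sugar transporters, ribosomal proteins (at a median of -0.014), DNA replication, proteasome and glycolysis, and the flbD deletion higher ribosomal proteins, DNA replication and heat shock proteins and lower lipases. The stuA deletion gained higher pectinases, chitin genes, mitochondrial respiration and glycolysis, and the flbB deletion higher secondary metabolism enzymes and lower mitochondrial respiration and oxidative stress defence. Lower calls were gained for cellulases, glycolysis and oxidative stress defence in wetA, for heat shock proteins, glycolysis, oxidative stress defence and ergosterol biosynthesis in abaA and for mitochondrial respiration in flbE. Unmatched random lists added lower cellulases in flbE, wetA and abaA, lower pectinases in flbE and abaA, lower secondary metabolism enzymes in flbD and higher ribosomal proteins in flbD. They also added higher heat shock proteins in flbB, flbE, wetA and abaA, higher mitochondrial respiration in flbB, flbD, abaA and stuA, higher glycolysis in flbA and higher oxidative stress defence in flbD and flbE. The filter at 5 added higher pectinases in stuA and lower secondary metabolism enzymes in abaA and stuA, no filter lower cellulases in wetA and pectinases in flbE, a pseudocount of 0.1 lower secondary metabolism enzymes in stuA and a pseudocount of 5 lower cellulases in wetA. Cytosolic ribosomal proteins alone were called lower in abaA and stuA, in stuA at a median of 0.11, since calls rest on the percentile and not on the sign of the median.

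With the median of the other 9 libraries as reference, the median of amylolytic enzymes was 0.13 in the flbC, 0.11 in the flbE, 0.38 in the stuA and 0.23 in the swi6 deletion. Nitrogen and amino acid uptake turned to -0.15 in abaA, -0.29 in flbC and -0.053 in swi6, and ribosomal RNA processing to -0.15 in flbA and -0.017 in flbC. Secondary metabolism enzymes had 0.40 in flbC, proteasome genes 0.049 in swi6, and ergosterol biosynthesis lay at 0.0069 in flbD, on the other side of random lists. Against unmatched random lists ribosomal proteins, at 0.031 in the flbE and 0.034 in the wetA deletion, moved to the upper side. The narrower cellulase list, chosen after seeing the data, lost the calls in the flbB, flbC and flbD deletions and kept that in stuA. Ribosomal proteins without the mitochondrial ones, also chosen after seeing the data, kept all 5 calls.

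The single genes that turned, among the pairs of gene and library that were tried, are as follows, as log2 differences from the median of the other 9 libraries. Regulators were PDE_00087 0.33 in abaA, 0.21 in flbC, 0.025 in flbD, 0.30 in wetA, and PDE_04095 0.19 in abaA, 0.18 in flbC, 0.30 in flbD. Genes listed for pigment, with the polyketide synthase PDE_09237, were PDE_09236 0.35 in flbB, 6.80 in flbC, 0.34 in flbE, 4.51 in swi6, PDE_09237 4.66 in flbC, 0.059 in flbE, 2.61 in swi6, 0.011 in wetA, PDE_09239 0.67 in abaA, 5.39 in flbC, 3.38 in swi6, 0.13 in wetA, PDE_09491 0.49 in flbB, 0.73 in flbC, 0.76 in flbE, and PDE_04496 0.22 in abaA, 1.17 in flbB, 0.80 in flbD, 0.84 in flbE. Wall and hydrolase genes were PDE_06621 0.38 in flbB, 0.78 in flbC, 0.63 in flbE, 0.18 in swi6, PDE_02648 0.45 in flbC, 0.088 in flbD, 0.012 in stuA, 0.29 in swi6, PDE_08139 0.73 in flbB, 0.13 in flbC, 0.10 in flbD, PDE_01168 1.76 in flbC, 0.23 in flbE, PDE_01573 -0.053 in flbB, PDE_01286 0.19 in flbD, PDE_03966 0.35 in swi6, and PDE_09417 0.52 in flbE. Peptidase and proteasome genes were PDE_01353 0.17 in flbB, PDE_07927 0.45 in flbC, and PDE_01514 0.12 in swi6. Heat shock genes were PDE_00322 -0.33 in flbA, and PDE_09235 0.64 in flbA. Ribosome genes were PDE_02554 -0.029 in flbB, -0.32 in wetA, PDE_05375 -0.0089 in wetA, and PDE_09977 -0.077 in flbE. Genes of metabolism were PDE_01345 -0.52 in flbC, -1.84 in wetA, PDE_04277 -0.0069 in flbD, PDE_04944 -0.063 in abaA, PDE_09230 0.32 in flbD, PDE_09761 0.15 in flbD, and PDE_09828 -0.66 in flbC.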

Other observations

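Several genes without an informative name, chosen after their values were seen, differed widely between libraries. PDE_00175 had 39.7 RPKM in wild type, 651 RPKM in the swi6, 1945 in the flbC, 2823 in the flbA and 4817 in the stuA deletion library, and 11114 to 19707 RPKM in the libraries labelled flbB, flbD, flbE, wetA and abaA deletion. PDE_02095 and PDE_02505 had 34.5 and 80.1 RPKM in wild type, at least 8827 and 10978 RPKM in the same 5 libraries, and 665 to 5622 and 1050.2 to 4749 RPKM in the other deletion libraries. PDE_04101 reached 20018 RPKM in the swi6 deletion library against 1307 in wild type and 8.04 in the flbA deletion library. PDE_09832 had 46346 RPKM in wild type, 22.9 in the flbA, 746 in the stuA and 500.4 in the swi6 deletion library. The very abundant short gene PDE_06605 had 203015 RPKM in wild type and was lowest in the stuA deletion library at 1938. PDE_00253 had 1 read in the flbE deletion library and 29 to 435 reads in every other library.

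Cytochrome P450 genes PDE_09199 and PDE_09202, also chosen after their values were seen, had 16.3 and 13.6 RPKM in the wetA and 22.4 and 16.9 RPKM in the library labelled abaA deletion. In wild type PDE_09199 had 0.621 RPKM and PDE_09202 had 0 reads. Cellulases chosen after their values were seen had low levels in these libraries. Cellobiohydrolase Cel7A-2 (PDE_07945) had 13.1 RPKM in wild type, 33.4 in the stuA and 7.38 in the library labelled flbD deletion, Cel6A (PDE_07124) had 2.08 to 9.84 RPKM, and the endoglucanase Cel7B (PDE_07929) 4.90 to 16.0 RPKM.

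A hypothesis formed after the values were seen is that the 204 genes higher in wild type than in every deletion library may lie in runs of neighbouring locus numbers, as genes of secondary metabolism clusters do. Among them 65 pairs carried neighbouring locus numbers, against a median of 4 and a highest value of 16 in random sets of 204 kept genes. The longest run took 21 genes from PDE_00789 to PDE_00811, with 17.2 to 235.8 RPKM in wild type and at most 11.5 RPKM in any deletion library, and holds the cytochrome P450 PDE_00811. The run PDE_09236 to PDE_09244 took 9 genes, among them those named scytalone dehydratase, monodictyphenone polyketide synthase and tetrahydroxynaphthalene reductase, at 91.5 to 864.9 RPKM in wild type. A run of 8 genes from PDE_10003 holds a gene named verruculogen synthase, a run of 5 genes from PDE_09229 a sterol demethylase, and a run of 4 genes from PDE_01069 a brevianamide F synthase, while a run of 4 genes from PDE_08155 has no informative name. Locus numbers stand here for position, and coordinates were not used here.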
